A study of Patiria miniata with 4 samples.

How the data were processed

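Single-cell transcriptomes of the bat star Patiria miniata, a sea star, were measured at 4 stages of development, with 1 library each of blastula, late gastrula, early larva and late larva. Per the labels, every embryo came from the same pair of parents, and fertilisations were staggered so that the stages were ready for dissociation together. Embryos were loosened in calcium-free sea water and an extraction medium for the hyaline layer, sheared with a pipette and passed through a mesh, and were never pelleted. Droplet libraries were made with the 10x Chromium 3' kit, which tags each captured polyadenylated molecule with a unique molecular identifier (UMI). A stage and a library therefore coincide, and no difference between stages has a replicate check.

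The deposited values were UMI counts per gene and barcode, whole numbers with no normalization, written by Cell Ranger 7.0.1, per the file headers. The submitters' processing notes name Cell Ranger and Seurat, and nothing in the matrices shows a Seurat step. The genome build and gene annotation behind the counts were not given in the sources used here. Each of the 4 matrices held exactly 12000 barcodes, 48000 in all, and 27818 features. The rule by which 12000 barcodes were kept was not given in the sources used here. The lowest UMI count of a barcode was 2401 in the blastula, 2383 in the late gastrula, 2685 in the early larva and 1959 in the late larva. Between 17.7% and 23.8% of barcodes lay within 10% of their library's lowest count, so each distribution ended abruptly on its shallow side. Cells with less RNA than that were not analysed here, and all shares of cells refer to the kept barcodes.

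Of the 27818 features, 26856 carried an NCBI locus number and 962 were tRNA features, and all 27818 matched the gene table of the Pmin_3.0 assembly. Neither the features nor that table paired a locus number with a gene name or product. The 29 gene lists fixed in advance (15 of cell types and 14 of pathways, 202 items) therefore matched 0 features. Cell type names, pathway lists, germ line transcripts, the mitochondrial share and scaling without ribosomal and mitochondrial genes could not be run. The gene table does give a class for each gene, and lists of long non-coding RNA (lncRNA), pseudogene, small nuclear RNA (snRNA) and small nucleolar RNA (snoRNA) genes were taken from it after the data were seen. No coordinates are given, since the build of the counts was not known to match.

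Barcodes were to be kept with at least 500 UMIs and at least 200 genes, and 0 barcodes failed. Scrublet, run per library in scanpy 1.11.5, called 0% of barcodes in each of the 4 libraries at its automatic threshold. It was judged not to have worked, and all barcodes were kept. Removing the 8% of barcodes with the highest doublet score was an alternative. For clustering, counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen by their ranks within libraries. The first 30 principal components and 15 neighbours gave a graph that was clustered by the Leiden algorithm (python-igraph 0.11.9) at resolution 1.0, without integration of libraries. Clusters were numbered by size.

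Since most clusters came from 1 library, clusters were compared between stages by their profile within their own library. A profile was the log2 ratio of CPM (UMI counts scaled to the library total) in the cluster to CPM in the library's other cells, with a pseudocount of 10 CPM, over 6599 genes with a mean of at least 20 CPM. Clusters with at least 50 cells in a library entered. Clusters of successive stages that were each other's best match with a Pearson r of at least 0.5 were joined into a family, named by a letter in order of size in the early larva. This matching was chosen after the data were seen. Changes within families were compared over genes with a mean of at least 50 CPM. To compare the spread of genes between cells, every cell was thinned to 1900 UMIs, which left out 0 cells, and the variance-to-mean ratio was computed for genes with a mean of at least 0.05 UMIs.

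For each library, counts were summed over cells and scaled to CPM. Log2 ratios between stages used a pseudocount of 1 CPM, and a gene was measured when its mean over the libraries was at least 1 CPM. Sums have exact 95% Poisson intervals, shares exact 95% Clopper-Pearson intervals and ratios exact conditional binomial intervals. All of these cover counting error only and treat UMIs as independent. They are too narrow for genes whose UMIs lie in few cells. With 1 library per stage no test between stages was run. The median of a gene list is set beside its percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

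Named genes followed a rule. For each pair of successive stages it takes the 10 genes with the largest and the 10 with the smallest log2 ratio. These need at least 100 CPM in either library and a gene name or product other than uncharacterized. For each cluster class it takes the 5 such genes with the largest mean log2 ratio to other cells, at 100 CPM or more in the class. For each list it takes up to 4 members, and germ line items are always given. No feature had a name, so the ranking was applied to locus numbers, with at most 2 printed in each direction of a comparison and the first 1 or 2 of a family. It was also applied to blastula against late larva. The comparisons, filters, clustering settings, named gene rule and most alternatives were chosen before the data were examined.

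The intervals, the search for overdispersed genes and the matching of clusters were tested on simulated data; the clustering, the doublet call and the correlations of changes within families were not. The true value of a ratio was that of the simulated shares of the library. Planted genes lower the share of all other genes, so the test covers counting error and not composition. For the ratios, counts were drawn as independent Poisson values, as the interval assumes, so coverage near 95% was favoured in advance. UMIs that lie clumped in few cells were not simulated there. With counts drawn from the real stage sums, the 95% interval of the ratio covered the true value for 95.7% of 15353 unchanged genes in late gastrula against blastula. It did so for 95.5% of 15371 in early larva against late gastrula, 95.5% of 15371 in late larva against early larva and 95.4% of 15354 in late larva against blastula. For 50 genes planted at each fold size, coverage in late gastrula against blastula was 98% at 2-fold, 90% at 4-fold and 94% at both 8-fold and 16-fold. In late larva against blastula it was 96%, 88%, 94% and 98% at the same sizes. In early larva against late gastrula it was 96%, 100%, 98% and 98%, and in late larva against early larva 92%, 96%, 96% and 98%. Simulated Poisson cells of each stage gave 0 genes with a variance-to-mean ratio above 2 (5320 genes tested in the blastula, 5539 in the late gastrula, 5260 in the early larva, 5342 in the late larva). All 50 planted overdispersed genes were found in each. The matching of clusters across the 3 later stages, over 6599 genes, recovered 4 of 6 planted groups when 400 genes changed per group and joined 0 wrong clusters. A further simulation with 1500 changed genes per group was added after that result and recovered 6 of 6, again with 0 wrong. The matching itself was not altered, so groups that differ in fewer genes can be missed. Each planted group had its own random set of changed genes, so wrong joins between similar groups were not tested.

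Alternatives were other cell filters, other resolutions, centring of genes within libraries, clustering of each library alone, the 6000 deepest barcodes and removal of high doublet scores. For family shares, levels and changes under another clustering, each cluster of a library went whole to the family that held most of its cells. For stage sums they were TMM factors from edgeR 4.0.16 in R 4.3.3, a pseudocount of 10 CPM, a minimum of 10 CPM and the mean over cells of each cell's own CPM. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.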

Results

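The series set out to describe the cell types of the sea star larva and holds 4 single-cell libraries, 1 per stage, titled day 1 (blastula), day 2 (late gastrula), day 3 (early larva) and day 4 (late larva). Each library had 12000 barcodes. Total UMIs were 55268891 in the blastula, 54887859 in the late gastrula, 69477803 in the early larva and 55569078 in the late larva. The median barcode had 3381, 3193.5, 3622.5 and 2507 UMIs in the same order, and 1848, 1721.5, 1788 and 1457 genes. Between 23447 and 23650 features had at least 1 UMI in a library. With 1 library per stage no difference between stages has a replicate check, and the 95% intervals given cover counting error only.

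The step from blastula to late gastrula was the largest between successive stages in these libraries. Genes that were abundant in the blastula were far lower: LOC119721314 went from 12887 CPM (12857 to 12917) to 180.4 CPM (177 to 184), and LOC119731328 from 2667 CPM (2653 to 2680.3) to 35.1 CPM (33.6 to 36.7). In the other direction, LOC119743461 went from 2.12 CPM (1.75 to 2.54) to 601 CPM (595 to 608), a 284-fold difference. LOC119738874 went from 1.79 CPM (1.46 to 2.18) to 250.0 CPM (246 to 254). Genes at least 4-fold lower in the late gastrula had held 9.98% of blastula UMIs, and genes at least 4-fold higher held 14.9% of late gastrula UMIs. Over 15572 measured genes the log2 CPM values of the libraries correlated at r = 0.865 (Spearman's rho 0.859), across genes, which are not independent replicates. The log2 ratios were -6.21 for LOC119731328, -6.15 for LOC119721314, 7.59 for LOC119743461 and 6.49 for LOC119738874. The 10 genes with the largest ratios, among 2419 with at least 100 CPM in either library, reached down to 5.89, and the 10 with the smallest up to -4.68.

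Late gastrula and early larva were much closer, and the largest differences were gains, while the median gene was slightly lower in the early larva (log2 ratio -0.12, quartiles -0.37 to 0.14). The lncRNA gene LOC119739610 went from 6.18 CPM (5.54 to 6.87) to 347 CPM (343 to 351), and LOC119740142 from 7.63 CPM (6.92 to 8.40) to 358 CPM (354 to 363). These are log2 ratios of 5.60 and 5.38. The genes that were lower differed less. LOC119723779 went from 319 CPM (314 to 323) to 48.1 CPM (46.5 to 49.8), a log2 ratio of -2.70, and LOC119734707 from 115 CPM (112 to 118) to 30.4 CPM (29.1 to 31.7), a log2 ratio of -1.89. Genes at least 4-fold higher in the early larva held 1.87% of its UMIs, while genes at least 4-fold lower had held 0.135% of late gastrula UMIs. The latter share was 0.0403% with a pseudocount of 10 CPM. Across genes the correlation was r = 0.957. TMM scaling shifted the log2 ratios of this comparison by a median of 0.10, and the values here are relative to the whole library.

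Early and late larva were similarly close by correlation (r = 0.964 across genes), and the leading genes had different histories. LOC119744350 was at 3.27 CPM (2.86 to 3.72) in the early larva and 111 CPM (108 to 114) in the late larva, a 33.9-fold difference. LOC119744331 went from 29.4 CPM (28.1 to 30.7) to 482 CPM (476 to 488), a 16.4-fold difference. LOC119724507 went from 199 CPM (196 to 203) to 17.1 CPM (16.03 to 18.22), after a level of 204 CPM in the late gastrula and 2.46 CPM in the blastula. LOC119730233 was at 8122 CPM in the blastula and 124 CPM in the late gastrula, and went from 162 CPM (159 to 165) in the early larva to 19.4 CPM (18.3 to 20.6) in the late larva. Genes at least 4-fold lower in the late larva had held 0.569% of early larva UMIs, and genes at least 4-fold higher held 1.45% of late larva UMIs.

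From the first stage to the last, a large part of the transcript pool was exchanged. Genes at least 4-fold lower in the late larva had held 23.6% of blastula UMIs, and genes at least 4-fold higher held 25.2% of late larva UMIs, with r = 0.764 across genes. LOC119726585 went from 0.760 CPM (0.548 to 1.03) to 1252 CPM (1243 to 1262), and LOC119726584 from 1.07 CPM (0.813 to 1.38) to 1377 CPM (1367 to 1386). LOC119731328 and LOC119721314, the genes that were lowest against the blastula in the late gastrula, went on down to 1.42 CPM (1.13 to 1.77) and 18.2 CPM (17.1 to 19.3). Genes at least 4-fold above each of the other 3 stages held 7.93% of UMIs in the blastula and 1.09% in the late larva. They held only 0.0533% in the late gastrula and 0.0140% in the early larva. The middle stages had a sampled neighbour on each side and the end stages did not, so these shares are not directly comparable.

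**Figure D1:**
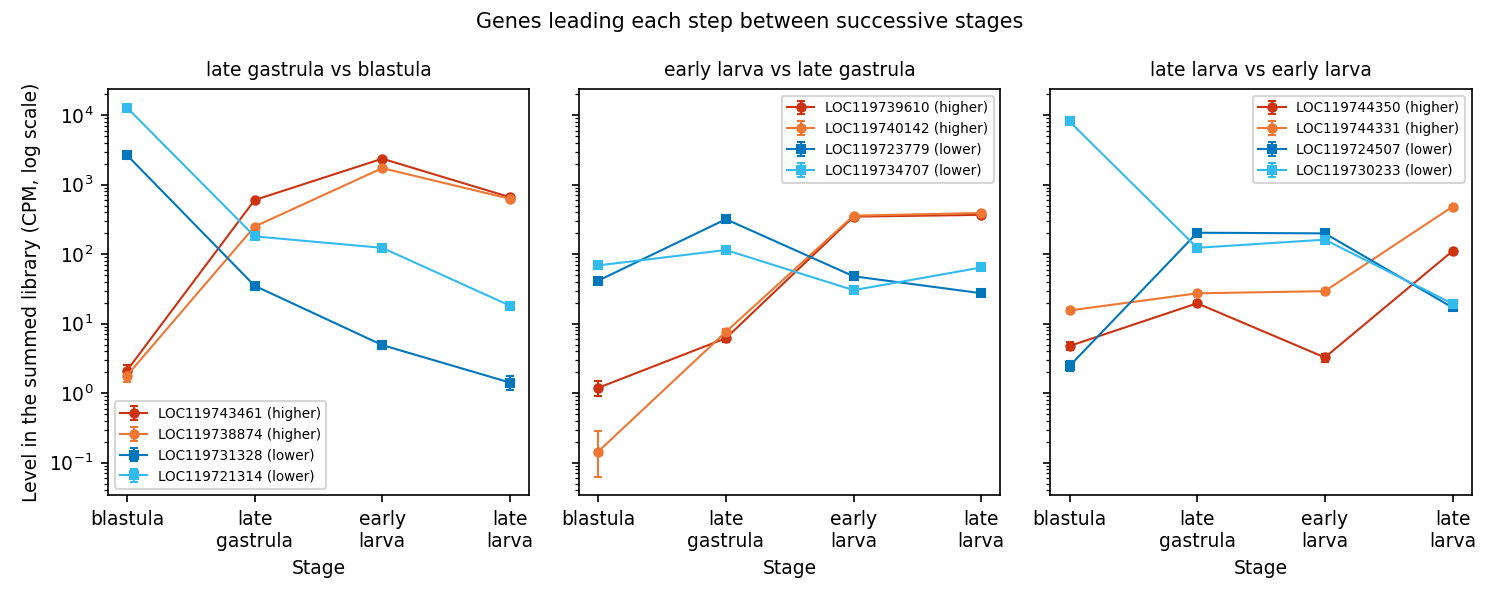
Level in the summed library (CPM, log scale) of the genes leading each step between successive stages, by stage, with 1 library per stage. Points are sums over 12000 barcodes and bars the 95% Poisson interval. LOC119721314 goes from 12887 CPM in the blastula to 18.2 CPM in the late larva, and LOC119740142 from 7.63 CPM in the late gastrula to 358 CPM in the early larva.

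Classes of RNA also differed by stage. Genes annotated as lncRNA held 2.13% of UMIs in the blastula, 3.59% in the late gastrula, 3.75% in the early larva and 3.93% in the late larva. A few abundant genes made up much of that: LOC119740317 stood at 2818, 6306, 7304 and 14207 CPM over the 4 stages, and LOC119722795 at 1853, 9116, 10635 and 7995 CPM. Single lncRNA genes went both ways. The median log2 ratio of the 804 measured lncRNA genes was 0.01 for late gastrula against blastula (quartiles -0.76 to 0.61), below all 10000 matched random lists, whose median was 0.16. It was -0.13 for early larva against late gastrula (percentile 0.15) and 0.08 for late larva against early larva (percentile 88.9). The last value turned to -0.10 among lncRNA genes with a mean of at least 10 CPM. For late larva against blastula the median was -0.00 (quartiles -1.14 to 0.90), below all 10000 random lists (their median 0.18), and -0.18 at a mean of at least 10 CPM. The value for early larva against late gastrula was -0.26 at that minimum, -0.06 with TMM factors, -0.04 with a pseudocount of 10 CPM and -0.08 with cells weighed equally.

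Transcripts of snRNA genes, which belong to the splicing machinery, were highest in the blastula. They held 0.0189% of its UMIs, against 0.00349% in the late gastrula, 0.00377% in the early larva and 0.00199% in the late larva. The 16 measured snRNA genes had a median log2 ratio of -1.82 for late gastrula against blastula and -2.41 for late larva against blastula, each below all 10000 random lists. It was 0.01 for early larva against late gastrula (percentile 71.3) and -0.43 for late larva against early larva (percentile 0). With a pseudocount of 10 CPM the same medians were -0.70, -0.85 and, for late larva against early larva, -0.08. With cells weighed equally the median for early larva against late gastrula was 0.11. The 4 measured snoRNA genes had medians of -1.58 for late gastrula against blastula (percentile 0.04), -0.13 for early larva against late gastrula (percentile 43.1), -0.36 for late larva against early larva (percentile 3.08) and -1.91 for late larva against blastula (percentile 0.1). The 209 measured pseudogenes had medians of 0.02, -0.10, 0.11 and 0.17 for the 4 comparisons (percentiles 1.59, 36.8, 95.3 and 45.6) and also went both ways, with quartiles of -0.42 to 0.65 for late gastrula against blastula and -0.53 to 0.76 for late larva against blastula. Features of tRNA genes were also highest in the blastula, at 0.00612% of UMIs against at most 0.00256% later. Those of rRNA genes were at 0.00470% against at most 0.00286%, so the higher share was not particular to snRNA genes. A kit that captures polyadenylated RNA counts few of these RNAs, and all values for them rest on low CPM.

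Cells of all stages clustered together fell into 25 clusters, and 18 of these took at least 90% of their cells from 1 library. Those 18 held 88.1% of cells (87.8 to 88.3), and a cluster of that kind can reflect its library as well as a cell type. After each gene was centred within its library the share was 17.7%. Compared by their profiles within their own library, clusters of successive stages formed 11 families, labelled A to K. Of these, 6 were found in the late gastrula, early larva and late larva, a number that was 11 with centred genes and 12 with each library clustered alone. The 7 links between late gastrula and early larva had r from 0.623 to 0.829 and the 10 links between early and late larva r from 0.709 to 0.924. Families covered 99.3% of late gastrula, 98.6% of early larva and 99.6% of late larva cells. No blastula cluster reached the r of 0.5 needed to join a family. The early larva clusters of families H, K and I had their best late gastrula matches in families B, E and G, at r of 0.585, 0.556 and 0.524, which were not reciprocal, so the absence of these families from the late gastrula does not mean that related cells were missing.

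The 3 large families of the larvae were A, B and C. Family A (cluster 5 in the early larva, 4 in the late larva), led by LOC119720180, held 30.2% (29.4 to 31.0) and 32.2% (31.3 to 33.02) of the cells of these libraries. Family B (clusters 7, 8 and 12 in the late gastrula, early larva and late larva), led by LOC119731350, held 24.8%, 22.4% and 14.1%. Family C (clusters 1, 10 and 9), led by LOC119741784, held 46.1%, 18.1% and 20.9%. In the late gastrula only 6.02% of its cells had a UMI of that gene after thinning, against 3.03% of other cells (12.2% and 5.74% before thinning). The late gastrula cluster of family C matched early larva cluster 10 at r = 0.623, the weakest link of all. It was also the best late gastrula match of cluster 5 of family A, at r = 0.499. That match was under the bound and not reciprocal. The 46.1% can therefore include cells that resemble family A, for which no late gastrula cluster was found. Family C cells held 47.7% of late gastrula UMIs, 34.001% of early larva UMIs and 47.9% of late larva UMIs. The genes that lead a family differed in level between stages, so no direction is drawn from these shares. At resolution 0.5, with each cluster given whole to 1 family, family A held 48.9% and 60.1% of the larval cells and family C 9.18% and 12.1%. Family C also held 8.10% of the early larva after the 8% of barcodes with the highest doublet scores were removed.

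Among the smaller families, family H (cluster 22 in both larvae) held 2.81% of early larva cells and 1.94% of late larva cells. Its first leading gene, LOC119736997, had 1762 CPM inside it in the early larva. After thinning to 1900 UMIs, 71.5% of its early larva cells had a UMI of that gene, against 1.64% of other cells (81.0% and 2.96% before thinning, at median depths of 4306 and 3608 UMIs). Family D (clusters 17, 15 and 14), led by LOC119738868, held 6.24%, 8.34% and 10.1% of the 3 later libraries, and 9.66% of the late gastrula with genes centred. Family E (clusters 11, 11 and 16), led by LOC119730839, held 9.75%, 5.11% and 6.43%, and 1.79% of the late larva at resolution 0.5. Family F (clusters 13, 13 and 23), led by the lncRNA gene LOC119744339, held 6.65%, 3.95% and 4.72%. Family G (clusters 21, 21 and 19), held 1.73%, 3.08% and 5.05%. Its first gene by ratio, LOC119737697, was found in few of its cells, and the second, LOC119746059, in 43.8%, 49.1% and 58.4% of them after thinning, against 0.975%, 2.04% and 5.30% of other cells (53.4%, 61.2% and 64.4% against 1.93%, 4.28% and 8.67% before thinning). Family I (cluster 20), led by LOC119723541, held 1.67% and 3.27% of the early and late larva. Family J (cluster 18), led by LOC119741108, held 3.94% of the late gastrula and 1.58% of the early larva, and 1.03% of the 6000 deepest early larva barcodes. Its early larva cluster also matched late larva cluster 16 of family E at r = 0.669, though not as each other's best, so that cluster can include cells like those of family J. Family K (cluster 24), led by LOC119733922, held 1.29% and 0.867% of the larval libraries, and 1.31% of the late larva with each library clustered alone. At resolution 2.0 family K kept only 0.00833% of late larva cells, under the rule that gave each cluster whole to 1 family.

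**Figure D2:**
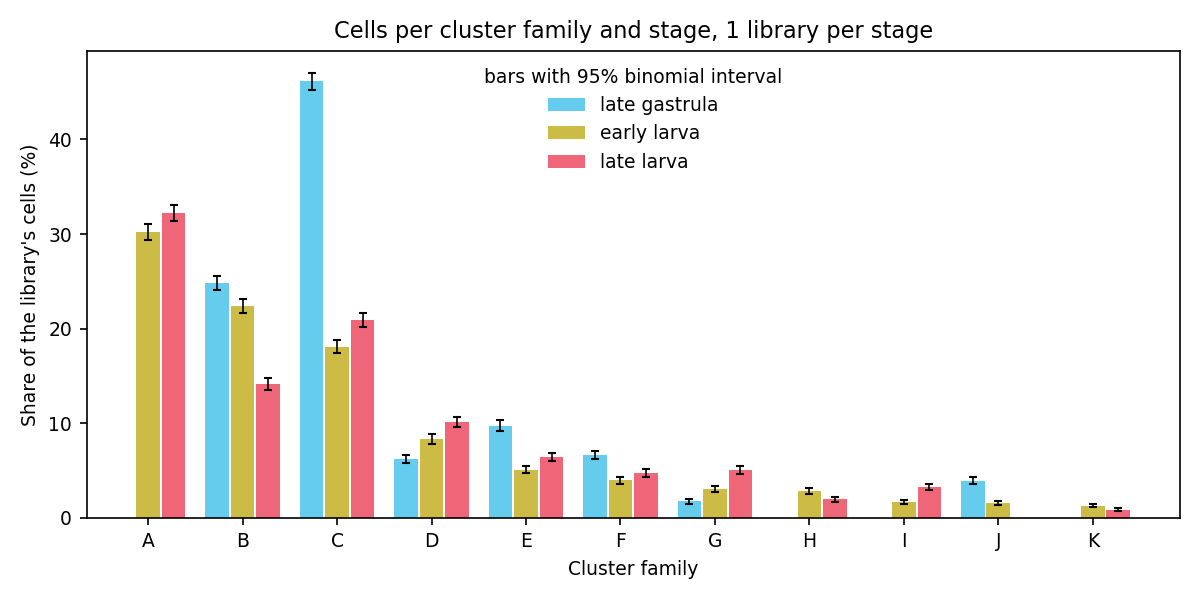
Share of each library's cells (percent) in cluster families A to K in the late gastrula, early larva and late larva, with 1 library of 12000 barcodes per stage and 95% binomial intervals as bars. A missing bar means that no cluster of that stage joined the family. Family C held 46.1% of late gastrula cells and family A 30.2% of early larva cells.

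The blastula held 4 clusters of its own. Cluster 2 had 37.4% of its cells, cluster 3 had 32.96%, cluster 6 had 28.4% and cluster 25 had 1.17%. Cluster 3 was marked by LOC119726374 at 407 CPM (397 to 416) and LOC119734459 at 479 CPM (469 to 489), and it held 90.1% and 89.6% of the blastula UMIs of these genes. In the late gastrula LOC119734459 had its highest level in family B, at 816 CPM (801 to 831), and LOC119726374 in family E, at 262 CPM (248 to 278). The best match of cluster 3 was family E of the late gastrula, with r = 0.448. Clusters 2 and 6 differed from the rest of the blastula by less. The first leading gene of cluster 2, LOC119720793, had a log2 ratio of 0.98 and that of cluster 6, LOC119731780, 1.16. The median depth was 3797 UMIs in cluster 2, against 3190 in other blastula cells, and 2946 in cluster 6, against 3650. Whether the split of these clusters follows depth was not tested. Cluster 25 (140 cells) had as its first gene LOC119725669, with 1106 CPM (1025 to 1192), and held 80.8% of the blastula UMIs of that gene. Only 12.1% of its cells had a UMI of the gene after thinning, against 0.405% of other cells (13.6% and 0.776% before thinning, at median depths of 3108 and 3382 UMIs). The level therefore rests on few cells, and its interval does not cover the spread between cells.

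Several genes that led the stage comparisons belonged to particular families. Family H held 84.1% of early larva UMIs of LOC119740142 and 67.1% of its late larva UMIs. It likewise held 88.9% and 75.5% of the UMIs of LOC119726585, and 89.5% and 74.6% of those of LOC119726584. LOC119726585 reached 20855 CPM in family H of the early larva and 52479 CPM in that of the late larva, against 98.3 and 531 CPM in family A. After thinning, 15.9% of early larva and 54.1% of late larva cells outside family H had a UMI of LOC119726585. Its level in all cells outside family H was 87.5 and 312 CPM. Free RNA was not measured, so the levels outside family H, including those in family A, can follow family H and need not be expression by those cells. LOC119738874 was shared by family B (4377 CPM) and family H (18526 CPM) in the early larva. LOC119743461 had its highest level in family B, which held 66.8%, 61.4% and 45.2% of its UMIs in the late gastrula, early larva and late larva. Family H followed, with 4736 CPM in the early larva (7009 CPM in family B) and 1382 CPM in the late larva (2927 CPM in family B). The lncRNA gene LOC119739610 was likewise high in families B and H, at 1020 and 1086 CPM in the early larva and 2045 and 1345 CPM in the late larva. LOC119724507 was at 717 CPM in family B and 842 CPM in family H of the early larva, and at 106 and 82.9 CPM in the late larva. LOC119744331 had 607 CPM (547 to 672) in blastula cluster 25, and 1411 CPM (1388 to 1435) in family A of the late larva.

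**Figure D3:**
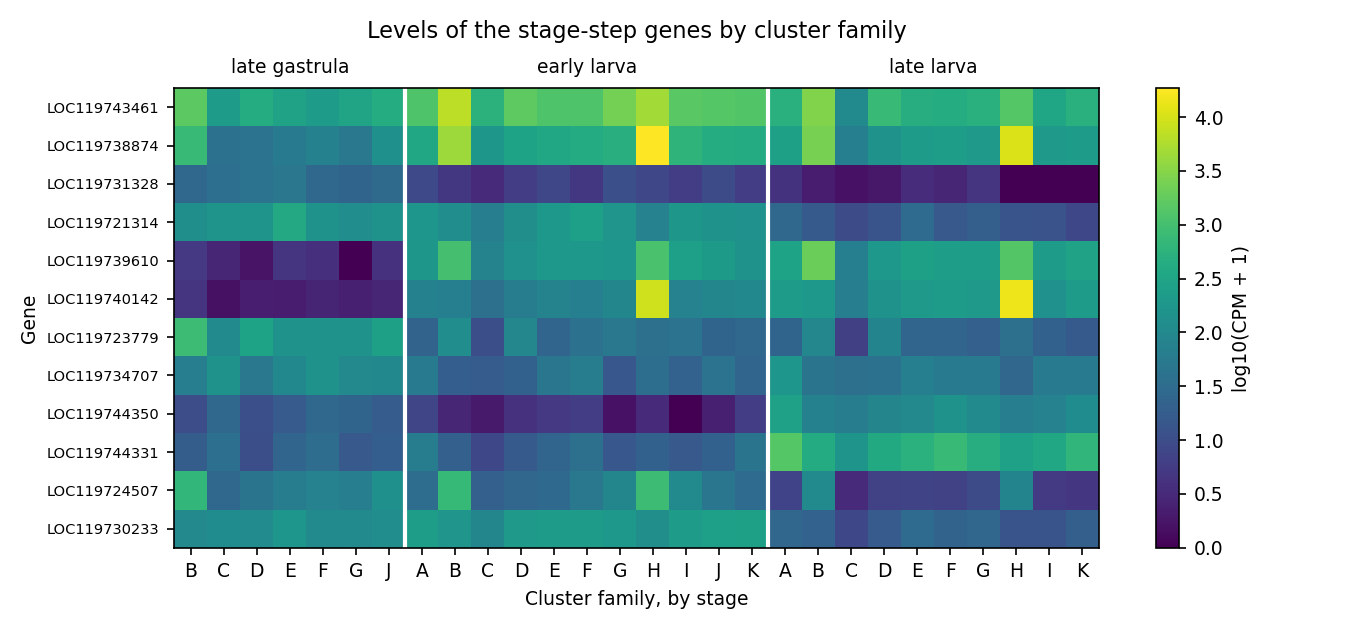
Level of the genes leading the steps between successive stages (color, log10 of CPM plus 1) in each cluster family, for the late gastrula, early larva and late larva, with 1 library per stage. Families with at least 50 cells are shown. LOC119738874 is brightest in family H, at 18526 CPM in the early larva, and LOC119743461 in family B.

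The change from early to late larva was largely shared by the families, and that from late gastrula to early larva less so. From early to late larva, the log2 ratios of 3475 genes correlated between pairs of the 10 families at a median r of 0.808 (0.698 to 0.913 over 45 pairs). LOC119744331 had log2 ratios between 3.75 in family H and 4.99 in family G, and LOC119730233 between -2.87 in family G and -4.08 in family I. From late gastrula to early larva the median over 21 pairs of 7 families was 0.717 (0.465 to 0.792). The 6 pairs with family C were the lowest, from 0.465 to 0.582, and all others were at 0.613 or more. LOC119723779 was lower in each of these 7, from -1.56 in family G to -3.49 in family J, and at 855 and 122 CPM in family B. These correlations are across genes, and a shift of a whole library enters all of its families alike. Free RNA was not measured, and family B held 68.0% of the late gastrula UMIs of LOC119723779, so its lower levels in the other families can follow family B.

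Cells became more unlike each other after the blastula by the spread of single genes. At 1900 UMIs per cell, 54 of 5379 genes had a variance-to-mean ratio above 2 in the blastula, 129 of 5681 in the late gastrula, 277 of 5493 in the early larva and 269 of 5602 in the late larva. The order of the early and late larva turned at a ratio of 1.5, with 522 and 544 genes, against 114 in the blastula and 315 in the late gastrula. At 1000 UMIs per cell the 4 counts were 20, 62, 121 and 112. In the blastula LOC119729334 had the highest ratio, 10.999, and 1% of cells held 75.9% of its thinned UMIs.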

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

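Tests chosen only after the data were seen were all alternatives for changes within families and for the spread of genes, the 6000 deepest barcodes, the mean over cells and the minimum of 10 CPM for correlations and stage shares, and removal of high doublet scores for levels within families. No paired analysis was possible because each stage had 1 library and no result came from a test. The cell filters and keeping of doublets moved no value because 0 barcodes failed them. Summing all deposited barcodes moved none for the same reason. Not run were the germ line alternatives and scaling without ribosomal and mitochondrial genes, since no gene could be named. The snRNA list at 10 CPM was not run because too few members were left, and the share of cells in single-library clusters with each library clustered alone would be complete by construction. Unless stated, the cause of a difference was not tested. The directions of the 16 leading gene ratios held under each setting run. Among list medians clearly off 0, 1 turned: the median of lncRNA genes for late larva against early larva went from 0.08 to -0.10 among genes of at least 10 CPM. Medians near 0, such as that of lncRNA genes for late gastrula against blastula, were not judged by sign. The order of early and late larva by the spread of genes also turned at a variance-to-mean ratio of 1.5.

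With a pseudocount of 10 CPM, which shrinks ratios of low genes by construction, the correlation was 0.875 for late gastrula against blastula, 0.966 for early larva against late gastrula and 0.789 for late larva against blastula. The share of earlier UMIs in genes at least 4-fold lower was 8.58%, 0.0403%, 0.474% and 20.5% for the 4 comparisons in order, and that of later UMIs in genes at least 4-fold higher 13.1%, 1.53%, 1.14% and 22.4%. The lncRNA medians were -0.0385 and 0.0226 for the steps to early and late larva. The snRNA medians were -0.70 (late gastrula against blastula), -0.0836 (late against early larva) and -0.85 (late larva against blastula). With TMM factors the shares in lower genes were 11.035%, 0.102%, 0.718% and 24.4%, those in higher genes 12.3%, 2.15%, 1.32% and 23.5%, and the lncRNA medians -0.0559 and 0.0208.

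With cells weighed equally the correlation was 0.861 for late gastrula against blastula, 0.960 for late against early larva and 0.742 for late larva against blastula. Shares in lower genes were 9.75%, 0.104%, 0.456% and 23.5%, and in higher genes 13.3%, 2.14%, 1.62% and 18.2%. The lncRNA median for early larva against late gastrula was -0.0785, and the snRNA median 0.11. With genes of at least 10 CPM only, the 4 correlations were 0.759, 0.928, 0.939 and 0.588. The lncRNA medians were then -0.26 for early larva against late gastrula and -0.18 for late larva against blastula.

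The share of cells in clusters of mainly 1 library was 89.3% at resolution 0.5, 97.3% at resolution 2.0, 88.6% without the highest doublet scores and 17.7% with genes centred within libraries, which removes differences between libraries by construction. Families in all 3 later stages numbered 11 with centred genes and 12 with libraries clustered alone. The median correlation of changes between families was 0.750 at a pseudocount of 1 CPM, 0.677 at resolution 0.5 and 0.681 without high doublet scores for early larva against late gastrula. For late against early larva it was 0.763 at resolution 0.5, 0.827 at resolution 2.0 and 0.791 without high doublet scores. Genes with a variance-to-mean ratio above 1.5 numbered 114, 315, 522 and 544 by stage, and those above 2 at 1000 UMIs per cell 20, 62, 121 and 112, where fewer UMIs lower the ratio by construction. Depth limits rare transcripts: 3 UMIs of a library equal 0.0543 CPM in the blastula and 0.0432 CPM in the early larva.

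Other results are given as counts. Of the 16 leading gene ratios, 16 moved with a pseudocount of 10 CPM, 12 with cells weighed equally and 5 with TMM factors, no log2 value by more than 1.5 times. Folds have no pseudocount and shrink more with one by construction: with 10 CPM the log2 ratio was 5.66 instead of 7.59 for LOC119743461 and 3.19 instead of 4.71 for LOC119744350. Shares of the blastula clusters were not run under other settings. Of 28 family shares, 23 moved in the 6000 deepest barcodes, 16 with centred genes and 13 with libraries clustered alone, each time with 1 share moving more than 1.5 times. At resolution 0.5, 7 of 21 moved and 5 of these by more than 1.5 times. At resolution 2.0, 7 of 27 moved, and 12 of 27 without the highest doublet scores, each with 1 by more than 1.5 times. The rest of the 28 shares had no value under these settings, because no cluster went to the family at that stage. They were not counted as moved, so these counts leave out the families that were lost and understate the change. Levels of leading genes in their families moved for 18 of 42 at resolution 0.5 (4 by more than 1.5 times, all in the late larva), 9 of 52 at resolution 2.0 and 26 of 54 without the highest doublet scores (0 by more than 1.5 times in these settings). The 4 were LOC119720180 (223 to 132 CPM) and LOC119720035 (260.2 to 158 CPM) in family A, and LOC119730839 (262 to 121 CPM) and LOC119724265 (413 to 128 CPM) in family E.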

Other observations

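The depth test of family C, the free RNA test and the test for late larva cells in the blastula were set before their results were seen. The other tests here, and the choice of the rare genes described next, came after. In the late larva 3 genes were found almost entirely in the same few cells. LOC119720809 had 89.7% of its UMIs in 8 cells with at least 10 UMIs of it, LOC119719907 had 91.4% in 6 cells and LOC119719824 had 94.6% in 9 cells. All 6 cells of LOC119719907 were among those of LOC119720809, where chance overlap would be 0.0040 cells, and 7 cells were shared by LOC119719824 and LOC119720809, against 0.0060 by chance. LOC119720809 made up as much as 19.7% of the UMIs of 1 cell. These cells did not form a cluster: the largest group among the 9 was 3 cells in family C, and among the 6 it was 3 in family G. The library levels of the genes were 15.7, 2.82 and 0.864 CPM in the early larva and 50.4, 24.9 and 28.4 CPM in the late larva.

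Family G was the largest group for several other genes of this kind, in mostly separate cells. It was not so for all of them. Of the 32 late larva cells with at least 10 UMIs of LOC119736987, 13 were in family C, the largest group. For LOC119728293 in the late gastrula, 11 of 30 such cells were in family C, again the largest group. In the early larva LOC119737697 had 92.1% of its UMIs in 43 cells, 17 of them in family G, and up to 17.4% of the UMIs of 1 cell. LOC119732283 had 75.8% of its UMIs in 66 cells, 48 of them in family G. The 2 genes shared 5 cells, against 0.236 by chance over the whole library. That value ignores that many cells of both genes lay in family G, so more overlap would be expected. After thinning, 8.94% of early larva family G cells had a UMI of LOC119737697, against 2.66% of other cells, at median depths of 3506 and 3625 UMIs. In the blastula, 29 of the 33 cells with at least 10 UMIs of LOC119729334 were in cluster 25. The gene stood at 29.1 CPM in that library and at 298, 915 and 1013 CPM in the later stages.

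Some of the 140 cells of blastula cluster 25 carried transcripts that were high in different families later: LOC119725669 had 1106 CPM there and 2939 CPM in family D of the late larva, and LOC119744312 had 356 CPM there, 108 CPM in family E of the late gastrula and 204 CPM in family A of the late larva. After thinning, 12.1% and 16.4% of the 140 cells had a UMI of these genes, against 0.405% and 0.278% of other cells (13.6% and 17.9% against 0.776% and 0.506% before thinning). A mix of cells like the whole late larva library is argued against. The 50 genes highest in late larva against blastula reached a median of 5.78% of their late larva level in these cells. Those genes came from library sums. Family H held 75.5% and 74.6% of the late larva UMIs of the first 2, LOC119726585 and LOC119726584. Cells of another late larva family could therefore score low, and this stays open. LOC119744637, at 673 CPM in the late larva, had 913 CPM in cluster 25 and 7.94 CPM in other blastula cells. Droplets that mix other clusters at their mean levels are argued against as well. Of 50 genes that led one part of the 140 cells, 100% exceeded every other blastula cluster by a set margin in the remaining part. The cluster was formed from all 140 cells, so the parts are not independent, and mixtures of unusual cells are not excluded. Whether the 140 cells were an early form of a later family stays open. Their profile correlated at no more than 0.164 with any later cluster, below the lower bound set against an early form. The other blastula clusters were above that bound (0.461, 0.466 and 0.330 for clusters 2, 3 and 6). None of them reached the bound of 0.5 set for an early form either, so a low value cannot decide.

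Family C held 34.001% of early larva and 47.9% of late larva UMIs in 18.1% and 20.9% of cells, and 25.1% of its late larva cells had more than 10000 UMIs, against 1.42% of other cells. Its profile was not confined to its deepest cells: the profile from cells of middle depth correlated with that from all cells at 0.896 or more in both larvae. Those cells were placed in family C by the same expression and are part of all its cells. A high value was therefore favoured in advance, and depth as a source of the profile stays open. Mixtures of other clusters are argued against, since 84% of its 50 leading early larva genes exceeded every other late larva cluster by the same margin. The late larva profile of family C correlated at 0.346 with the blastula to early larva ratio, against 0.0824 for the next family. This met the bound set for a blastula-like transcript pool after the data were seen. Against it, 9 of the 10 genes lowest in the late larva against the blastula were below their library level in family C, though several of them were near 1 CPM or less in that library, so it stays open, as do droplets with several family C cells or clumps, which were not tested.

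From early to late larva genes moved together in all families, with a median correlation between families of 0.808. A technical shift of 1 whole library and a true change of stage cannot be told apart, because each stage had 1 library. Free RNA carrying the rising genes into all families also stays open: the 113 rising genes had in their lowest family a median of 45.6% of the library level, against 18.0% for 50 genes that lead a family. That ratio of 2.53 lay between the bounds of 1.5 and 3 set for and against free RNA, so it may account for part of the shared rise.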
